A study of Homo sapiens with 40 samples.

How the data were processed

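Gene expression was measured on 40 single-colour Illumina bead arrays in 4 human mantle cell lymphoma lines, GRANTA519, JEKO1, MAVER1 and REC1. Per the labels, each line was exposed to the BET bromodomain inhibitor OTX015 or to DMSO, its solvent, and was sampled after 2, 4, 8, 12 and 24 h, with 1 array for each line, treatment and time. The 10 groups of treatment and time thus held 4 arrays each, and the replicates of a group were the 4 cell lines. The dose of OTX015, and whether the times of a line came from separate cultures, are not given in the sources used here. RNA was extracted with TRIzol and passed a quality check at an integrity number above 8, and biotin-labelled cRNA was made with the Ambion TotalPrep kit, per the labels' protocols.

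The deposited non-normalized table gave 1 intensity for each of 47231 probes on each array, between 70.92 and 22105, exported with GenomeStudio per the submitters' processing notes (its version is not given in the sources used here). The table held signals alone, so detection p-values and control probes were not used here. The authors' series matrix gave deposited log2 values of the same arrays, not centred by probe, with column medians between 6.706 and 6.707. Each of its 40 columns correlated best with its own array and kept the order of that array's signals up to a backward step of 0.005 log2. The normalization behind the series matrix is not given in the sources used here, and its values served as an alternative. No array was left out.

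The comparisons, their tests, the gene lists, the rule for the named genes and most alternatives were fixed before the data were examined. The normalization fixed then, neqc of limma, needs control probes or detection p-values and was replaced. The background level of an array was taken as the mode of its log2 signal density, and its spread from the signals below the mode. These levels lay between 88.9 and 112.2 intensity units. The signals were corrected with the normal-exponential model at those values, an offset of 16 was added, and the arrays were quantile normalized and put on the log2 scale with limma 3.58.1 in R 4.3.3. Quantile normalization gives all arrays the same distribution, so a change shared by all transcripts would not be seen. A probe counted as detected on an array where its signal exceeded the mode by 2.33 SD, which corresponds to a one-sided p of 0.01. Of all probes, 27864 were detected on at least 4 arrays and were kept.

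The annotation used here gave 1 gene symbol for 30113 probes and several for 8, and 17110 probes were unnamed here. Symbols were brought up to date through Entrez ids against a RefSeq gene table of the assembly GRCh38.p14, used for names and gene lengths only, and 30074 probes matched and 47 did not. Each gene was represented by its probe with the highest mean, which left 13959 genes. Detection of a gene refers to the probe that represents it. Where that probe was detected on no array of 1 arm, the difference is given as "at least N-fold". This bound is the mean of the detected arm against the mean, over the arrays of the other arm, of the higher of the lowest signal among detected probes and the probe's own signal, and none is given where it is under 1.

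All tests of OTX015 used the 20 differences in log2 signal between the OTX015 and the DMSO array of the same line and time. Arrays of the same line and time deviated together from their group means (correlation across genes 0.753 to 0.885 over the 20 pairs), because they share a cell line. After the mean of each line was removed these correlations lay between -0.258 and 0.0924. The effect at each time was a coefficient over 4 lines with the spread shared over the 5 times, and the effect over all times was tested on the 4 line means. The effect in each line was a coefficient over its 5 times, with the spread shared over the 4 lines. Its p-value thus measures the spread over times and not over cultures. Lines that do not detect a gene add little to the shared spread, so the p-value in another line may be too small. Differences between lines and between times were tested with F tests in a model with line and time, and the change from 2 h to 24 h as a contrast. The 20 DMSO arrays were fitted with line and time. In tests between lines the 5 times of a line again stand in for replicates, so those p-values do not measure the spread over cultures. All used limma's lmFit and eBayes with two-sided p-values and Benjamini-Hochberg adjustment over the 13959 genes, at an adjusted p of 0.05.

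A set of 30 gene lists was tested with camera of limma at a preset correlation of 0.01 and again with the correlation estimated from the data, and adjusted over the 30 lists, or over 150 tests of a list at a time. Members of a list that passed are counted with adjustment over all genes and, where said, adjusted over the list alone. The text names genes by this rule. Over all times it takes the 12 largest rises and 12 largest falls among genes past the threshold with the same sign in all 4 lines, and at each time the 5 largest of each kind. For the change from 2 h to 24 h, and for DMSO at 24 h against 2 h, it takes the 5 largest rises and falls. For each F test it takes the 8 genes with the smallest p, within each line the 5 largest rises and falls with the same sign at all 5 times, and from each list up to 4 members with the largest change. MYC, HEXIM1, BRD2, CCND1, CDK4, CDK6, CDKN1A, BCL2, BCL6, MCL1, BTK, CD79A, CD79B, MYD88, IRF4, SOX11 and E2F1 are always reported, and 1 further gene fixed with them is not reported here. A gene that the text names outside this rule is said to be chosen after its values were seen.

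The steps were tested on simulated data, in which 200 of 13959 genes were changed. Of changes of 1 on the log2 scale, 100% were recovered over all times, 91% at 2 h, 94% in REC1, 78% between lines, 50% between times and 61% from 2 h to 24 h. Of changes of 0.5, these shares were 91%, 33%, 45%, 12%, 3% and 6%. Of 100 unshifted lists of 30 genes, 4 fell under an unadjusted camera p of 0.05. The simulated noise was independent between genes, so this rate does not carry over to lists of correlated genes. It was also independent between the times of a line, so the recovery over all times may be too favourable.

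The alternatives tried were no background correction, an offset of 50, scaling to a common median, the authors' series matrix values, no filter on detection, detection on all 40 arrays, the mean of all probes of a gene, an intensity trend in eBayes, other treatments of the pairing and of the spread, leaving out the 2 h or the 24 h arrays, leaving out each line in turn, and the estimated correlation for lists. A further pair of alternatives was chosen after seeing the data. They leave out the JEKO1 pair at 12 h, whose OTX015 array had the highest background, and the 2 h arrays in tests where this had not been planned.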

Results

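Genome-wide expression was measured in GRANTA519, JEKO1, MAVER1 and REC1, established lines of mantle cell lymphoma, a B cell cancer that as a rule overexpresses cyclin D1. The lines were exposed to OTX015, a small molecule that occupies the acetyl-lysine pocket of the BET proteins, or to DMSO. Each of the 10 groups of treatment and time held 4 arrays, 1 per line, so that 20 OTX015 arrays each had a DMSO array of the same line and time. Between 36.4% and 49.2% of the 47231 probes were detected on an array, and the median signal of an array lay between 95.57 and 125.6. Each of the 40 arrays correlated best with another array of its own line. Values below are OTX015 minus DMSO on the log2 scale, as mean ± SD of 4 lines unless said otherwise, with adjusted p-values of limma over 13959 genes. Their size depended on the background correction. Among 168 named changes of at least 2-fold, the median change was 63.1% of the size given here without background correction and 59.8% with the authors' series matrix values.

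The comparison over all times asks which genes OTX015 changed in these lines irrespective of time. Histone genes, TUFT1 and ZSWIM6 were among the largest rises, and TNFRSF17 and FCMR among the largest falls, in all 4 lines. H2BC5 and H2BC21, which encode histone H2B, rose 5.12-fold each (log2 2.36 ± 0.41 and 2.36 ± 0.46, adjusted p = 0.000557 and 0.000661). TUFT1, which encodes tuftelin, rose 4.62-fold (log2 2.21 ± 0.25, adjusted p = 0.000275), and ZSWIM6 rose by 1.83 ± 0.17 (adjusted p = 0.000275). In JEKO1 TUFT1 was detected on 0 DMSO arrays and was at least 3.56-fold higher, so background limits the size of its rise there. TNFRSF17, the BCMA receptor of plasma cells and late B cells, fell (measured log2 -3.15 ± 0.70, adjusted p = 0.000678) and was detected on 20 DMSO arrays and 6 OTX015 arrays, so that the size of its fall is limited by the background. FCMR, the Fc receptor for IgM, changed by -2.23 ± 0.47 (adjusted p = 0.000665).

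In all, 1993 genes rose and 1974 fell over all times, of which 87 and 177 changed at least 2-fold. The 12 largest rises further held H2AC6 (2.24 ± 0.69), H4C14 (2.08 ± 0.69), H4C15 (2.01 ± 0.70), H2BC11 (1.85 ± 0.36) and H2AC18 (1.81 ± 0.37), all core histone genes. Among them were also FGFR3, a fibroblast growth factor receptor (2.11 ± 0.34, adjusted p = 0.000495), and PPP1R13B, which encodes the p53-binding protein ASPP1 (1.99 ± 0.53, adjusted p = 0.00107). FGFR3 was detected on 0 DMSO arrays of JEKO1 and MAVER1 and was at least 2.58-fold and 2.42-fold higher there. The size of its mean rise, also at single times, is thus limited by the background. EFR3B, whose product anchors a lipid kinase at the plasma membrane, was detected on 18 OTX015 arrays and on 0 of the 20 DMSO arrays, at least 4.55-fold higher (adjusted p = 0.000688). It had 3 probes, of which 1 carried the rise, and their mean rose by 0.92. The mean of all probes also gave smaller values for FGFR3 (1.12) and for ACSL5 (-1.09).

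The 12 largest falls further held SLC2A5, a fructose transporter (-2.28 ± 0.52), NAPSB (-2.25 ± 0.40), GAPT, a B cell adaptor protein (-2.24 ± 0.31), and TLR10, a toll-like receptor of B cells (-2.15 ± 0.61). The others were ACSL5, a fatty acid CoA ligase (-2.05 ± 0.30), SLC15A3, a lysosomal peptide transporter (-2.04 ± 0.36), PCED1B (-2.04 ± 0.48), ESPNL (-1.97 ± 0.58), CD72, a coreceptor of the B cell receptor (-1.96 ± 0.68), and SH3TC1 (-1.93 ± 0.63). Their adjusted p-values lay between 0.000391 for GAPT and 0.00203 for CD72. GAPT was at least 3.29-fold lower in JEKO1, where 0 OTX015 arrays detected it. The count of 3967 genes was 2467 without GRANTA519 and 2419 without MAVER1. At an unadjusted p of 0.05, 5566 genes passed, against 698 expected by chance.

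Of the 30 gene lists, 15 passed the camera test over all times, 6 higher and 9 lower. With an estimated correlation 0 of 30 passed after adjustment, and 4 had an unadjusted p under 0.05. Over all times that test has only the few degrees of freedom of 4 line means, so a list could hardly pass. The list of BET proteins and P-TEFb lost its call although its estimated correlation, -0.052, lay below the preset 0.01. A failure here thus does not show that correlation within a list explains its call. The tests at single times used the spread of 20 differences. Among 20 measured histone genes 18 rose and 0 fell (19 and 0 adjusted over the list alone), with a median of 1.18 and adjusted p = 6.04e-12, but adjusted p = 0.240 with an estimated correlation. The list of BET proteins and P-TEFb, the kinase that releases paused RNA polymerase II, also holds inhibitors of P-TEFb, elongation factors and SERTAD1. As a list it rose by a median of 0.44, with 8 members up and 2 down (9 and 2 adjusted over the list alone, with adjusted p = 0.00931, and adjusted p = 0.271 with an estimated correlation). This median does not show that the kinase itself rose. This list did not pass among genes detected on all 40 arrays (median 0.38, adjusted p = 0.0668). SERTAD1 rose by 1.58 ± 0.23, the elongation factors ELL2 and AFF4 by 0.80 and 0.70, and the P-TEFb inhibitor HEXIM1 by 0.59 ± 0.34, while HEXIM2 and LARP7, which hold P-TEFb inactive and were chosen after their values were seen, fell (-0.36 and -0.26). Of 8 response markers of BET inhibitors taken from general knowledge, 5 rose and 2 fell (5 and 3 adjusted over the list alone; median 0.61, adjusted p = 0.105). ZCCHC24 rose by 1.29 ± 0.18 and H2BC12 by 1.30 ± 0.59. CCR2 fell by 0.80 ± 0.67 (adjusted p = 0.04), a call that ended in 8 of 15 alternatives (adjusted p 0.000341 to 0.102), among them those without GRANTA519 (0.076) and without MAVER1 (0.102). In MAVER1 0 OTX015 arrays detected CCR2, which was at least 1.29-fold lower there.

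Lists of B cell identity and signalling fell. Of 31 measured genes of B cell receptor signalling, 19 fell and 2 rose (19 and 4 adjusted over the list alone; median -0.43, adjusted p = 0.000991, and adjusted p = 0.465 with an estimated correlation). Besides CD72, the phosphatase PTPN6 (-1.61 ± 1.01), the kinase BLK (-1.19 ± 0.35) and the inhibitory receptor FCGR2B (-1.01 ± 0.28) fell. Without GRANTA519 or MAVER1 PTPN6 did not pass (-1.48 and -1.55, adjusted p = 0.0621 and 0.0608, range over 15 alternatives 3.89e-05 to 0.0621), and the mean of its probes changed by -0.88. Of 27 genes of toll-like receptor and MYD88 signalling, 15 fell and 1 rose (15 and 2 adjusted over the list alone; median -0.32, adjusted p = 0.000135, and adjusted p = 0.271 with an estimated correlation). This list did not pass among genes detected on all 40 arrays (median -0.17, adjusted p = 0.0963). TLR7 (-1.62 ± 0.41) and TLR9 (-1.34 ± 0.09), both sensors of nucleic acids, fell, and the interferon regulator IRF7 rose by 1.41 ± 0.36. Of 26 B cell transcription factors, 15 fell and 1 rose (16 and 2 adjusted over the list alone; median -0.38, adjusted p = 0.00034, and adjusted p = 0.271 with an estimated correlation). Falls included SPI1 (-1.5 ± 0.26), IKZF1 (-1.11 ± 0.18) and POU2AF1 and POU2F2, which act together at octamer promoters (-0.88 ± 0.33 and -0.87 ± 0.41).

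Plasma cell markers fell in 9 of 16 cases and rose in 2 (the same counts adjusted over the list alone; median -0.42, adjusted p = 0.0085, and adjusted p = 0.271 with an estimated correlation). This list did not pass among genes detected on all 40 arrays (median -0.12, adjusted p = 0.145). After TNFRSF17 the largest were TNFRSF13B (-1.35 ± 0.70) and JCHAIN (-1.21, adjusted p = 0.0165). In REC1 JCHAIN was not detected, so no fall could be seen there. JCHAIN did not pass without GRANTA519 (-1.18, 0.066), JEKO1 (-1.01, 0.0569) or MAVER1 (-1.05, 0.0735; range over 15 alternatives 0.000962 to 0.0735). Of 14 measured MHC class II genes, 6 fell over all genes tested and 14 adjusted over the list alone (median -0.53, adjusted p = 0.000108, and adjusted p = 0.503 with an estimated correlation). This list did not pass among genes detected on all 40 arrays (median -0.46, adjusted p = 0.0769), and its medians in GRANTA519, JEKO1, MAVER1 and REC1 were -0.77, -1.01, -0.31 and -0.0074. HLA-DMB changed by -1.32 ± 0.46 and HLA-DOB by -1.26 ± 0.56, both parts of the peptide-loading machinery. HLA-DPB1 had -0.72 ± 0.66 (adjusted p = 0.0529) and was not detected in REC1. It passed in 7 of 15 alternatives, among them without REC1 (0.00681; range 0.00141 to 0.175). Chemokine receptors and adhesion genes fell in 9 of 17 cases and rose in 1 (10 and 1 adjusted over the list alone; median -0.64, adjusted p = 0.000742, and adjusted p = 0.271 with an estimated correlation). This list did not pass among genes detected on all 40 arrays (median -0.27, adjusted p = 0.0963). GPR183, which guides B cells within lymphoid tissue, changed by -1.54 ± 0.92 and the sphingosine phosphate receptor S1PR4 by -1.13 ± 0.41. In REC1 S1PR4 was detected on 0 OTX015 arrays and was at least 1.19-fold lower.

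Among 33 NF-kB targets 13 fell and 5 rose (14 and 5 adjusted over the list alone; median -0.22, adjusted p = 0.00885, and adjusted p = 0.570 with an estimated correlation). The NF-kB list did not pass among genes detected on all 40 arrays (median -0.044, adjusted p = 0.591), and its median in MAVER1 was 0.0039. The transcription factor BATF changed by -1.47 ± 0.50 and the cytokine gene LTB by -1.13 ± 0.52. In JEKO1 BATF was detected on 5 DMSO and 0 OTX015 arrays, at least 2.57-fold lower, and LTB on 1 and 0. Background thus limits the size of both falls. CCL3, a chemokine gene, fell by 1.15 ± 0.46, but not past the threshold without background correction (adjusted p = 0.0533) or with the series matrix (0.053; range over 15 alternatives 6.96e-07 to 0.0533). Interferon response genes fell in 10 of 34 cases and rose in 2, also adjusted over the list alone (median -0.31, adjusted p = 0.000466, and adjusted p = 0.381 with an estimated correlation). The interferon list did not pass among genes detected on all 40 arrays (median -0.14, adjusted p = 0.0668). The antiviral genes MX1 and OAS2 changed by -1.1 ± 0.62 and -1.01 ± 0.48, and the mean of all probes of OAS2 changed by -0.46. OAS2 was at least 1.28-fold lower in REC1, where 0 OTX015 arrays detected it. MYC targets fell in 28 of 51 cases and rose in 1 (30 and 1 adjusted over the list alone; median -0.25, adjusted p = 6.11e-09, and adjusted p = 0.381 with an estimated correlation). PPAN, a ribosome assembly factor (-0.85 ± 0.21), the folate carrier SLC19A1 (-0.83) and the coactivator PPRC1 (-0.81 ± 0.11) fell.

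Lists of metabolism and stress were higher or had mixed members. Cholesterol synthesis genes rose in 7 of 19 cases and 0 fell (8 and 0 adjusted over the list alone; median 0.18, adjusted p = 0.000429, and adjusted p = 0.271 with an estimated correlation), with TM7SF2 at 0.97 ± 0.16 and LSS at 0.70 ± 0.18. Lysosome and autophagy genes rose in 12 of 29 cases and fell in 1 (14 and 3 adjusted over the list alone; median 0.21, adjusted p = 0.000607, and adjusted p = 0.272 with an estimated correlation). The sialidase NEU1 rose by 1.17 ± 0.23, the autophagy kinase ULK1 by 0.85 ± 0.37, and the protease CTSS fell by 0.75 ± 0.24. CTSS was detected on 0 OTX015 arrays at 8, 12 and 24 h (at least 1.54-fold, 1.34-fold and 1.2-fold lower), so background limits the size of its fall. Glycolysis and hypoxia genes rose in 10 of 28 cases and fell in 1, also adjusted over the list alone (median 0.11, adjusted p = 0.027, and adjusted p = 0.271 with an estimated correlation). This list did not pass among genes detected on all 40 arrays (median 0.09, adjusted p = 0.11), nor without JEKO1 (0.0575, range over 14 alternatives 0.0169 to 0.271). NDRG1 rose by 0.97 ± 0.18 and the glucose transporter SLC2A3 fell by 0.84 ± 0.38. With 0 OTX015 arrays detected there, SLC2A3 was at least 1.6-fold lower in JEKO1 and at least 1.14-fold lower in REC1. Of 22 p53 targets 8 rose and 1 fell (9 and 1 adjusted over the list alone; median 0.17, adjusted p = 0.0326, and adjusted p = 0.427 with an estimated correlation), led by GADD45A at 1.01 ± 0.21, with a list median of -0.051 in GRANTA519. The p53 list did not pass among genes detected on all 40 arrays (median 0.16, adjusted p = 0.141), nor without MAVER1 (0.0547) or REC1 (0.0595; range over 14 alternatives 0.00556 to 0.427). Of 25 genes of the unfolded protein and amino acid stress responses 3 rose and 5 fell (median -0.04, adjusted p = 0.619), with TRIB3 at -1.11 ± 0.18 and ASNS, which makes asparagine, at 0.67 ± 0.05.

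The remaining lists did not pass. Immediate early genes had 9 of 27 members up and 2 down (median 0.16, adjusted p = 0.0866), among them JUN at 1.15 ± 0.34 and SPRY1 at -0.94 ± 0.30, and passed without GRANTA519 (0.0483; range over 14 alternatives 0.0483 to 0.427). BCL2 family and apoptosis genes had 4 of 25 up and 7 down (median -0.14, adjusted p = 0.0866). CFLAR, an inhibitor of caspase activation, changed by -1.17 ± 0.21, and BCL2L1, which encodes BCL-XL, by -0.71 ± 0.15. This list passed with no detection filter (0.0452) and with the mean of all probes (0.0483; range over 14 alternatives 0.0452 to 0.64). JAK-STAT and cytokine genes had 5 of 26 up and 4 down (median -0.04, adjusted p = 0.866), with STAT3 at 0.71 ± 0.13 and the receptor IL21R at -1.1 ± 0.43. The RNA polymerase II and mediator list had 1 of 26 up and 3 down (median -0.01, adjusted p = 0.833), with POLR2A, its largest subunit, at 0.96 ± 0.14 and MED24 at -1.02 ± 0.21.

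Cell cycle lists went both ways. G1/S and DNA replication genes had 5 of 43 up and 9 down (median -0.01, adjusted p = 0.587), of which the polymerase subunit POLE2 (-0.86 ± 0.08) and E2F2 (-0.57 ± 0.21) fell. G2/M and mitosis genes had 4 of 38 up and 8 down (median -0.05, adjusted p = 0.475), of which UBE2C fell by 0.50 ± 0.14 and ANLN rose by 0.41 ± 0.10. Among cyclin D, CDK4/6 and CDK inhibitor genes 4 of 14 rose and 1 fell (median 0.01, adjusted p = 0.831), with the inhibitor CDKN2D at 1.08 ± 0.18 and CCND3 at 0.57 ± 0.27. Heat shock genes had 2 of 15 up and 1 down (median -0.01, adjusted p = 0.643). HSPB1 fell by 0.39 ± 0.08. Without the 24 h arrays it had a smaller change of -0.24 and did not pass (adjusted p = 0.0749, range over 16 alternatives 0.000836 to 0.0749). Ribosomal protein genes had 2 of 37 up and 1 down (median 0.01, adjusted p = 0.499), of which RPS7 fell by 0.53 ± 0.13. RPL13 was 0.30 higher (adjusted p = 0.0237), but its probes disagreed and their mean was -0.032 (adjusted p = 0.735, range over 16 alternatives 8.14e-05 to 0.735). Reference genes had 3 of 13 up and 0 down (median 0.05, adjusted p = 0.332), with SDHA at 0.43 ± 0.16.

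Markers of other cell types gave the background. T and NK cell markers had 0 of 8 measured members past the threshold (median -0.16, adjusted p = 0.403), and myeloid markers had 0 of 10 (median 0.02, mean -0.04, adjusted p = 0.833). Of 9 markers of non-blood cells 1 rose and 2 fell (median -0.13, adjusted p = 0.332). PECAM1, an adhesion molecule that B cells also carry, fell by 1.29 ± 0.18 (adjusted p = 0.000557).

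Genes of interest in mantle cell lymphoma and BET inhibition were read in the same test. BCL2, which blocks apoptosis, fell by 0.48 ± 0.12 (adjusted p = 0.00342) and its relative MCL1 rose by 0.58 ± 0.12 (adjusted p = 0.00219). The B cell kinase BTK (-0.62 ± 0.33, adjusted p = 0.0111) and the adaptor MYD88 (-0.63 ± 0.19, adjusted p = 0.0028) fell. So did CD79A and CD79B, the signalling chains of the B cell receptor (-0.59 ± 0.42 and -0.52 ± 0.28, adjusted p = 0.0281 and 0.0134). BRD2 rose by 0.53 ± 0.13 (adjusted p = 0.00289), HEXIM1 had an adjusted p of 0.0145, SOX11, a transcription factor expressed in most mantle cell lymphomas, rose by 0.44 ± 0.18 (adjusted p = 0.00905), CDK4 fell by 0.35 ± 0.13 (adjusted p = 0.0126) and CDKN1A rose by 0.42 ± 0.28 (adjusted p = 0.0288). MYC (-0.48 ± 0.50, adjusted p = 0.0865), CCND1 (-0.47 ± 0.85, adjusted p = 0.267), CDK6 (-0.13 ± 0.16, adjusted p = 0.243), BCL6 (0.15 ± 0.38, adjusted p = 0.469), IRF4 (0.20 ± 0.16, adjusted p = 0.111) and E2F1 (0.12 ± 0.19, adjusted p = 0.332) did not pass.

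Some of these genes did not pass with 3 lines, at changes close to those of 4 lines. Without GRANTA519 these were CDK4 (-0.32, adjusted p = 0.0565), CDKN1A (0.46, 0.073), CD79A (-0.64, 0.0707) and CD79B (-0.49, 0.0595), and without MAVER1 they were CDK4 (-0.30, 0.0575), CDKN1A (0.34, 0.109) and CD79A (-0.59, 0.0891). CDKN1A also did not pass without REC1 (0.36, 0.0972) and with no detection filter (0.0567), nor did CD79A with no detection filter (0.0641), and MYC passed without JEKO1 (0.0379, at -0.65) and with detection on all 40 arrays (0.0436). Over all alternatives the adjusted p ranged from 7.49e-06 to 0.0575 for CDK4, 0.000394 to 0.109 for CDKN1A, 0.000133 to 0.0891 for CD79A, 2.9e-06 to 0.0595 for CD79B and 0.000591 to 0.218 for MYC.

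**Figure D1:**
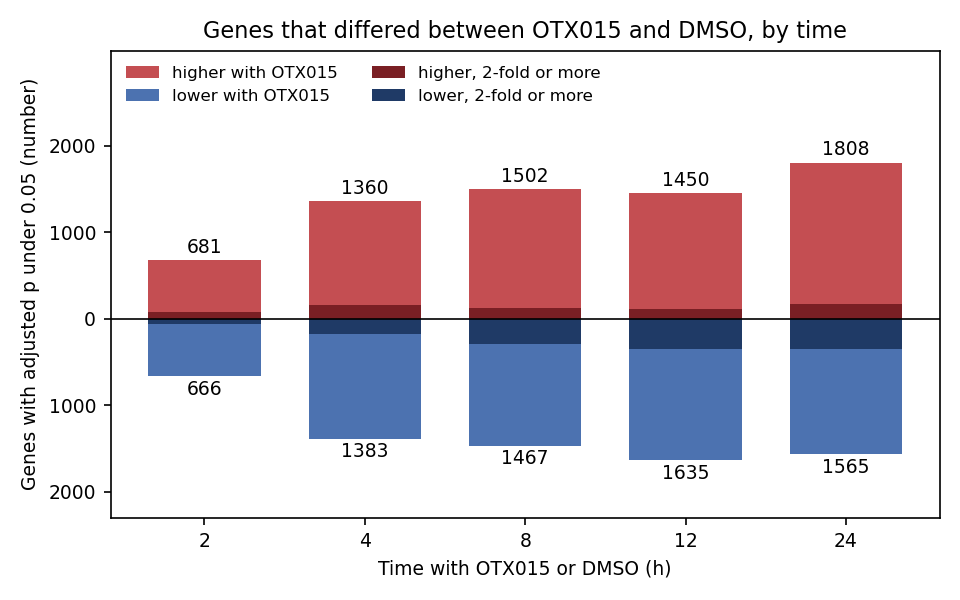
Number of genes that rose (upward bars) and fell (downward bars) with OTX015 against DMSO at each time in hours, over 4 lines, with changes of at least 2-fold in the darker part. The total went from 1347 genes at 2 h to 3373 at 24 h, and the genes that fell at least 2-fold from 55 to 343.

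The comparisons at single times ask when these changes appeared. After 2 h 681 genes rose and 666 fell, and 81 and 55 did so at least 2-fold. The largest rises were of BAMBI, a decoy receptor of TGF-beta signalling (2.24 ± 0.43, adjusted p = 0.000111), H2BC21 (2.14 ± 0.63), the transcription factor gene CSRNP2 (2.10 ± 0.39, adjusted p = 4.94e-07), TUFT1 (2.08 ± 0.18, adjusted p = 4.94e-07) and FAM222A (1.98 ± 0.46). The largest falls were of TLR10 (-1.87 ± 0.71), the chemokine genes CCL4L1 and CCL3L3 (-1.82 ± 1.05 and -1.81 ± 1.09), GPR183 (-1.74 ± 0.52) and TNFRSF17 (-1.73 ± 0.88). Over 15 alternatives CCL4L1 lay between -2.23 and -1.06 and CCL3L3 between -2.06 and -1.09. The count of 1347 genes was 708 without GRANTA519, 608 without MAVER1, 779 without REC1 and 303 with the spread of this time alone, under which CCL4L1 and CCL3L3 did not pass (0.0581 and 0.0635; ranges over 15 alternatives 0.00092 to 0.875 and 0.000898 to 1). TNFRSF17 did not pass without GRANTA519 (-1.82, 0.0602) or JEKO1 (-1.29, 0.123; range 0.00556 to 0.567), nor GPR183 without JEKO1 (-1.61, 0.122) or MAVER1 (-1.75, 0.135; range 0.00414 to 0.848).

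After 4 h TNFRSF17 fell by 3.43 ± 0.76 (adjusted p = 1.16e-05), the largest change of a gene detected in both arms. EFR3B was detected on 4 OTX015 and 0 DMSO arrays, at least 5.8-fold higher (adjusted p = 2.41e-06). TUFT1 rose by 2.68 ± 0.17 (adjusted p = 1.15e-08), PPP1R13B by 2.58 ± 0.71, FGFR3 by 2.53 ± 0.36 and H2BC21 by 2.45 ± 0.58. Falls were also seen for TLR10 (-2.32 ± 0.08), PCED1B (-2.30 ± 0.40), GAPT (-2.21 ± 0.37, adjusted p = 1.63e-06) and ESPNL (-2.09 ± 0.54). In all 1360 genes rose and 1383 fell, with 156 and 172 at least 2-fold. The count of 2743 was 1705 without MAVER1 and 1816 with the spread of this time alone, and the mean of all probes gave 1.05 for EFR3B and 1.42 for FGFR3.

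At 8 h EFR3B was at least 8.38-fold higher, H2BC5 rose by 2.53 ± 0.40 (adjusted p = 1.09e-06), FGFR3 by 2.44 ± 0.53, H4C14 by 2.38 ± 0.94 and H2AC6 by 2.37 ± 0.72. The largest falls were those of TNFRSF17 (-3.58 ± 0.63, adjusted p = 6.13e-06), FCMR (-3.07 ± 0.46, adjusted p = 2.16e-07), SLC2A5 (-3.04 ± 0.86), CD72 (-2.66 ± 0.82, adjusted p = 2.31e-05) and SLC15A3 (-2.59 ± 0.46). There were 1502 rises and 1467 falls, with 131 and 291 at least 2-fold. Without GRANTA519 2969 genes became 1867 and without MAVER1 1948, and FGFR3 was at 1.29 with the mean of its probes.

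By 12 h TNFRSF17 was detected on 4 DMSO and 0 OTX015 arrays, at least 9.21-fold lower (adjusted p = 3.91e-06). FCMR (-3.32 ± 0.71, adjusted p = 6.22e-08), ACSL5 (-3.30 ± 0.48, adjusted p = 6.52e-09), NAPSB (-3.23 ± 0.91, adjusted p = 3.97e-08) and SLC2A5 (-3.14 ± 0.69) fell. EFR3B was at least 6.77-fold higher, and H4C14 (2.46 ± 0.89), H2BC5 (2.37 ± 0.56), H2AC6 (2.33 ± 0.92) and H2BC11 (2.28 ± 0.52, adjusted p = 6.5e-07) rose. Rises numbered 1450 and falls 1635, with 115 and 349 at least 2-fold. The total of 3085 was 1973 without GRANTA519 and 1908 with the spread of this time alone, and the mean of all probes of ACSL5 gave -1.69.

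After 24 h 1808 genes rose and 1565 fell, 172 and 343 of them at least 2-fold. Falls were led by NAPSB (-3.55 ± 0.68, adjusted p = 8.09e-09), SLC15A3 (-3.43 ± 0.53, adjusted p = 5.17e-09), the pre-B cell gene VPREB3 (-3.38 ± 0.66, adjusted p = 2.05e-08) and ACSL5 (-3.34 ± 0.34, adjusted p = 3.21e-09). TNFRSF17 was at least 7.85-fold lower, with 0 OTX015 arrays detected (adjusted p = 1.03e-05). EFR3B was at least 6.42-fold higher, H2BC5 and H2BC21 rose by 2.78 ± 0.86 and 2.78 ± 0.79, H4C15 by 2.53 ± 0.56 and H2AC11 by 2.47 ± 0.30 (adjusted p = 4.28e-08). With the spread of this time alone 3373 genes became 2008, and the mean of all probes gave -1.66 for ACSL5 and 1.36 for H2AC11.

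The 8 h and 12 h effects were alike across genes (r = 0.856), and so were those at 12 h and 24 h (0.838), while 2 h and 24 h gave 0.452. These are 3 of 10 correlations between times, taken across genes, which are not independent replicates. At 2 h and 24 h 357 genes rose and 272 fell in both, against 88.2 and 74.7 for independent lists, and 23 passed in opposite directions. At all 5 times 227 genes rose and 184 fell, and 78 passed in opposite directions at a pair of times.

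Gene lists differed in when they moved, read as tests at each time and not as a test between times. In 67 of 150 tests a list passed at a time, and in 28 with an estimated correlation. Histone genes passed at 2, 4, 8, 12 and 24 h with medians of 0.81, 1.01, 1.31, 1.42 and 1.64, and adjusted p between 0.023 and 0.0304 with an estimated correlation. Toll-like receptor and MYD88 genes passed at all 5 times, with 8 members down at 2 h and 13 at 24 h, and adjusted p between 0.0304 and 0.0387 with an estimated correlation. B cell receptor genes had 0 members down at 2 h (adjusted p = 0.981), 11 at 4 h (0.002, but adjusted p = 0.262 with an estimated correlation) and 16 at 12 h (0.000209, but 0.181). MHC class II genes had 0 members down at 2 h (adjusted p = 0.25), 5 at 8 h (0.000697, but adjusted p = 0.376 with an estimated correlation) and 9 at 12 h (8.29e-06, but 0.224). MYC targets had 11 members down at 2 h (9.42e-05, but adjusted p = 0.272 with an estimated correlation) and 31 at 24 h (1.84e-12, but 0.072). Immediate early genes passed at 4 h with 9 up and 1 down (adjusted p = 0.000797, and adjusted p = 0.049 with an estimated correlation), and at 24 h had adjusted p = 0.649.

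Heat shock genes were higher at 2 h, with 3 of 15 up (adjusted p = 0.00234, but adjusted p = 0.15 with an estimated correlation). The chaperone genes HSPA1B, BAG3 and DNAJB1 rose by 1.57, 1.09 and 1.08 at 2 h (adjusted p = 0.00089, 0.00136 and 6.91e-06). At 24 h 5 heat shock genes fell and 0 rose (adjusted p = 0.00342, but adjusted p = 0.166 with an estimated correlation). In DMSO alone HSPA1B, BAG3 and DNAJB1 rose by 1.82, 0.72 and 0.95 from 2 h to 24 h (adjusted p = 0.00466, 0.00431 and 0.00326), so these courses are not those of the OTX015 arrays only. Cholesterol synthesis genes rose in 9 of 19 cases at 4 h (adjusted p = 2.07e-05, and adjusted p = 0.0357 with an estimated correlation), and at 24 h had 5 up and 2 down (adjusted p = 0.845). Plasma cell markers at 24 h had 10 of 16 members down and 2 up (adjusted p = 0.000561, and adjusted p = 0.0304 with an estimated correlation).

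**Figure D2:**
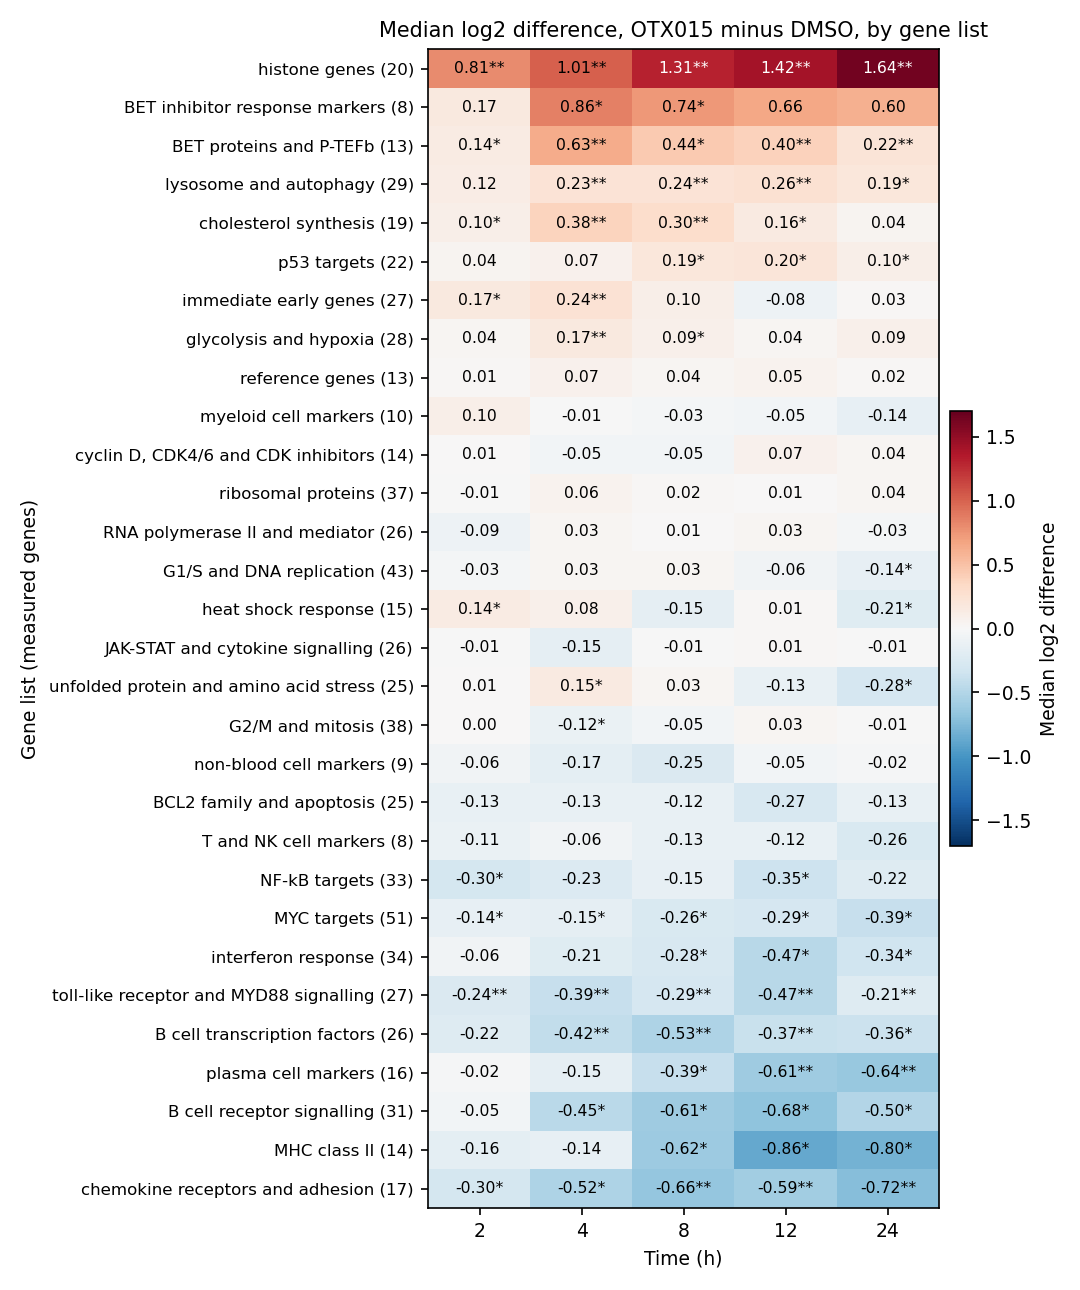
Median OTX015 minus DMSO log2 change of the measured genes of 30 gene lists (vertical, number of genes in parentheses) at each time in hours (horizontal), with 1 asterisk where a list passed with the preset correlation and a double asterisk where it also passed with an estimated one. Histone genes went from 0.81 at 2 h to 1.64 at 24 h, and MHC class II genes from -0.16 at 2 h to -0.86 at 12 h.

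The change from 2 h to 24 h asks which effects grew or turned. SLC15A3 went from -0.21 at 2 h to -3.43 at 24 h, a difference of -3.23 (SE 0.25, n = 4 lines, limma adjusted p = 1.14e-06). ACSL5 went from -0.18 to -3.34 (difference -3.16, adjusted p = 1.14e-06), VPREB3 from -0.37 to -3.38 (-3.01, adjusted p = 4.3e-07), FCMR from -0.27 to -3.27 (-2.99, adjusted p = 1.14e-06) and NAPSB from -0.73 to -3.55 (-2.82, adjusted p = 4.4e-06). TP53INP1, which promotes autophagy and p53-driven cell death, went from -0.19 to 1.98 (difference 2.18, SE 0.23, adjusted p = 1.77e-05), and MCRIP1 from -0.12 to 1.81 (1.93, adjusted p = 3.33e-05). The small nucleolar and Cajal body RNA genes SNORD46 and SCARNA8 rose by 1.78 (SE 0.25) and 1.74 (SE 0.23) between these times. EFR3B, not detected on DMSO arrays, was detected on 2 OTX015 arrays at 2 h and 4 at 24 h (adjusted p = 2.28e-06).

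In all 786 effects rose and 773 fell from 2 h to 24 h, 83 and 254 of them by at least 2-fold. VPREB3 (-0.45, adjusted p = 0.025), NAPSB (-0.55, adjusted p = 0.00628) and MCRIP1 (-0.34, adjusted p = 0.0421) also differed between 24 h and 2 h in DMSO alone. The count of 1559 was 674 without GRANTA519, 747 without MAVER1 and 830 without REC1, and the mean of all probes of ACSL5 gave -1.52.

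Across the 5 times, 1542 effects differed by the F test. The 8 smallest p-values belonged to VPREB3, FCMR, FERMT3, IFITM2, ACSL5, IFITM1, GTF3C6 and SLC15A3, all of which were lower at 12 h and 24 h than at 2 h. VPREB3 ran through -0.37, -0.49, -1.48, -2.71 and -3.38 (adjusted p = 5.24e-07), and FERMT3, which activates integrins in blood cells, through -0.02, -0.42, -1.49, -2.02 and -2.03 (adjusted p = 1.17e-06). IFITM1 and IFITM2, which restrict virus entry, reached -1.52 and -2.20 at 24 h (adjusted p = 1.48e-06 and 1.17e-06). GTF3C6, a subunit of an RNA polymerase III factor, reached -2.35 (adjusted p = 1.48e-06). BCL6, a repressor of germinal centre B cells, passed at 24 h (0.93, adjusted p = 0.00606) and differed between times (adjusted p = 0.0177), as did BTK (-1.17 at 24 h, adjusted p for times 0.00279). The count was 2367 without background correction, 2364 with the series matrix, 495 without GRANTA519, 969 without JEKO1, 505 without MAVER1, 563 without REC1 and 503 without the 2 h arrays, the last chosen after seeing the data.

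**Figure D3:**
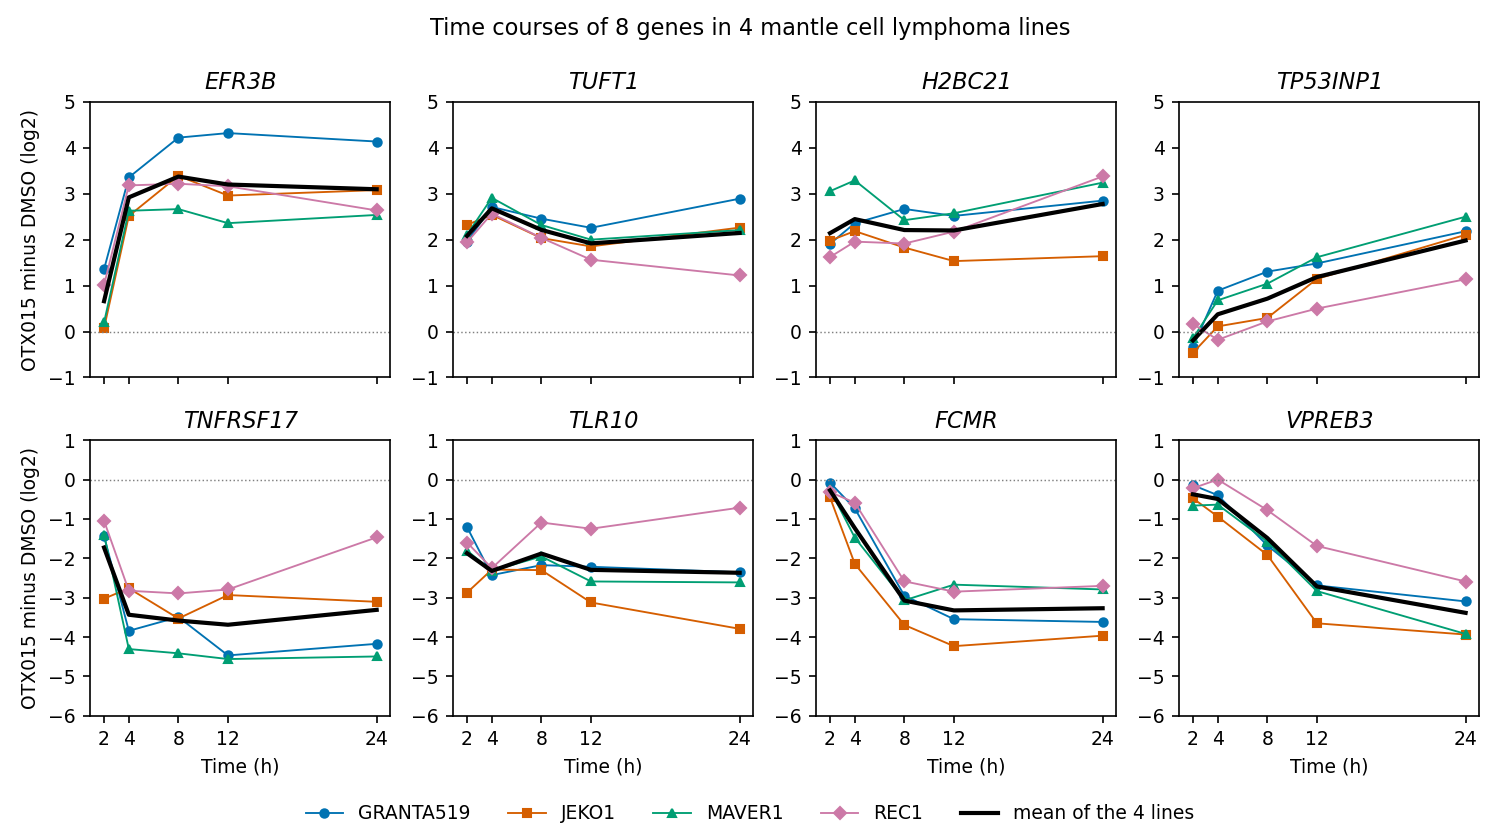
OTX015 minus DMSO log2 difference of 8 named genes (vertical) against time in hours (horizontal), with 1 coloured line per cell line and the mean of the 4 lines in black. TUFT1 and H2BC21 were already 2.08 and 2.14 higher at 2 h, whereas FCMR and VPREB3 were at -0.27 and -0.37 at 2 h and at -3.27 and -3.38 at 24 h.

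Effects within each line show how far the 4 lines shared the response. Values in these paragraphs are mean ± SD of 5 times. With the spread shared over the lines 3336, 3334, 3003 and 2116 genes passed in GRANTA519, JEKO1, MAVER1 and REC1. With the spread of each line alone these counts were 2877, 1894, 2313 and 2074. In GRANTA519 1631 genes rose and 1705 fell (196 and 284 at least 2-fold). EFR3B was at least 8.36-fold higher, H2AC6 rose by 2.86 ± 0.44 (adjusted p = 1.27e-08), EFNB2, a ligand of Eph receptors, by 2.75 ± 0.26 (adjusted p = 3.13e-08) and PPP1R13B by 2.55 ± 0.44. TNFRSF17 (-3.48 ± 1.2), GAPT (-2.67 ± 1.13, adjusted p = 2.06e-06) and KMO, an enzyme of tryptophan breakdown (-2.33 ± 0.65, adjusted p = 5.78e-08), fell. EFNB2 differed between lines (adjusted p = 6.05e-05). It was detected on 0 DMSO arrays of JEKO1, MAVER1 and REC1 and was at least 1.93-fold, 1.14-fold and 1.16-fold higher there, so the sizes of its rises cannot be compared.

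In JEKO1 1474 genes rose and 1860 fell, 105 and 359 of them at least 2-fold. DPYSL3, a cytoskeletal regulator of neurons, rose by 2.77 ± 0.81 (adjusted p = 4.49e-10), against 0.14 in GRANTA519 (adjusted p between lines 2.99e-06), and was not detected in MAVER1 and REC1. H4C15 rose by 2.27 ± 0.37, and EFR3B was at least 3.74-fold higher. The cadherin-related gene CDHR3 (-3.50 ± 1.95, adjusted p = 1.41e-06, between lines 0.00114), FCMR (-2.90 ± 1.59) and TLR10 (-2.87 ± 0.63, adjusted p = 6.15e-09) fell. CDHR3 was not detected in GRANTA519 and REC1 and was detected on 1 array of MAVER1. Such lines add little to the shared spread, so the p-value of CDHR3 in JEKO1 may be too small. TNFRSF17 and GAPT, not detected on the OTX015 arrays, were at least 5.68-fold and 3.29-fold lower.

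In MAVER1 1536 genes rose and 1467 fell (147 and 206 at least 2-fold). H2BC21 rose by 2.92 ± 0.40 (adjusted p = 1.42e-09), and EFR3B and FGFR3, not detected in DMSO, were at least 2.96-fold and 2.42-fold higher. TNFRSF17 fell by 3.83 ± 1.37. FCRL2, an Fc receptor-like protein of B cells, fell by 2.53 ± 0.995 (adjusted p = 1.39e-05), against -0.68, -1.65 and -2.24 in GRANTA519, JEKO1 and REC1 (adjusted p between lines 0.000952).

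In REC1 1068 genes rose and 1048 fell, 77 and 173 of them at least 2-fold. FGFR3 rose by 2.52 ± 0.50, and by 1.47 with the mean of its probes, and EFR3B was at least 4.64-fold higher. Falls included GPR183 (-2.52 ± 0.89, adjusted p = 9.33e-07), FCRL4 (-2.38 ± 1.44, adjusted p = 5.17e-05) and the interferon-induced chemokine CXCL10 (-2.27 ± 1.4, adjusted p = 4.06e-05). They differed between lines with adjusted p = 0.00358, 0.0243 and 0.00911, and FCRL4 was not detected in JEKO1. Without the 24 h arrays the count of 2116 was 1405.

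In all 4 lines 476 genes rose and 418 fell, and 34 passed in opposite directions in a pair of lines. GRANTA519 and MAVER1 shared 978 rises and 934 falls, against 179.5 and 179.2 for independent lists, and 2 genes were opposite. The correlation across genes between lines, which treats genes that are not independent replicates, lay between 0.656 for JEKO1 and REC1 and 0.764 for GRANTA519 and MAVER1 in 6 pairs of lines.

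Between lines, 1308 effects differed by the F test. Its p-values measure the spread over the 5 times and not over cultures of a line. FOXA2, a forkhead factor of endoderm, fell by 2.37 ± 0.17 in REC1 (adjusted p = 1.42e-14, between lines 1.41e-09) and was not detected on DMSO arrays of the other lines. CCND1, which encodes cyclin D1, was at least 2.20-fold lower in REC1, where 5 DMSO and 0 OTX015 arrays detected it (adjusted p = 1.64e-10, between lines 1.31e-06). It had -0.13 ± 0.31 in GRANTA519 and -0.08 ± 0.17 in MAVER1, and was not detected in JEKO1. In JEKO1, falls were those of VPREB1, of the pre-B cell receptor (-2.18 ± 0.39, between lines 2.04e-07), MYF6 (-1.79 ± 0.21), the podoplanin gene PDPN (-1.79 ± 0.52) and the claudin gene CLDN23 (-1.66 ± 0.29). MYF6 was not detected in GRANTA519, MAVER1 or REC1, VPREB1 was not detected in GRANTA519 and REC1 and was detected on 1 array of MAVER1, PDPN was detected on 0 DMSO arrays of MAVER1 and REC1, and CLDN23 was not detected in REC1. Where a gene was not detected, no fall could be seen. LFNG, a modifier of Notch receptors, rose by 2.03 ± 0.40 in GRANTA519 and 0.97 ± 0.38 in MAVER1 and had 0.00 in REC1 (between lines 3.84e-07). RTP4 fell by 1.75 ± 0.23 in MAVER1 and was at least 1.33-fold lower in GRANTA519 (between lines 1.31e-06), and it was not detected in JEKO1.

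MYC fell in GRANTA519 (-1.12 ± 0.29, adjusted p = 1.07e-06) and in REC1 (-0.58 ± 0.28, adjusted p = 0.00242), and had 0.04 in JEKO1 and -0.25 in MAVER1 (adjusted p between lines 0.000972). In the F test between lines FOXA2 and CCND1 did not pass without REC1 (0.815 and 0.737), nor VPREB1, MYF6, PDPN and CLDN23 without JEKO1 (0.139, 0.587, 0.512 and 0.16). The range over 13 alternatives began at 1.08e-12 for FOXA2, 5.55e-09 for CCND1, 7.8e-09 for VPREB1, 2.27e-08 for MYF6, 3.21e-08 for PDPN and 1.77e-09 for CLDN23, and ended at the values just given. The count of 1308 was 641, 721, 836 and 664 without GRANTA519, JEKO1, MAVER1 and REC1, and 687 among genes detected on all 40 arrays.

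**Figure D4:**
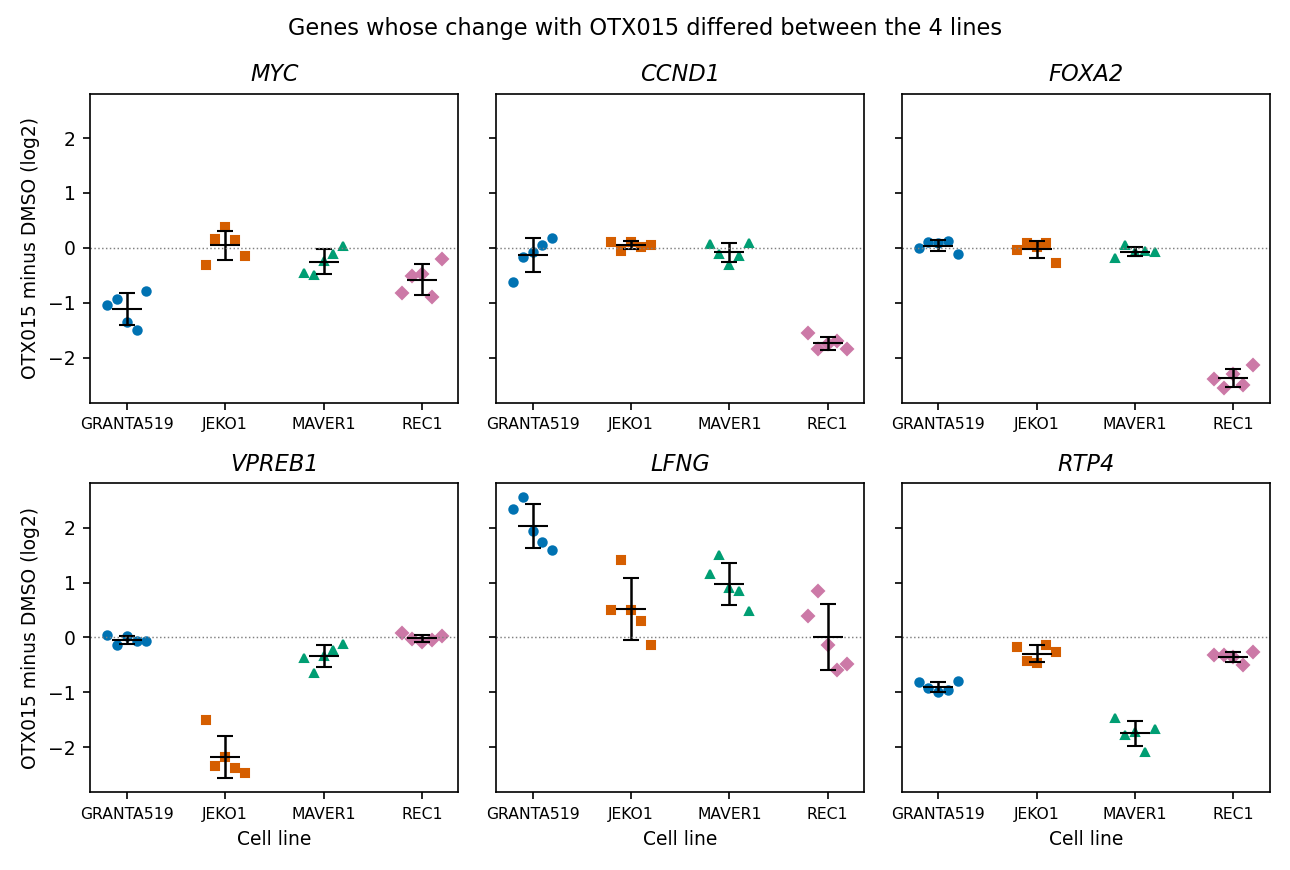
OTX015 minus DMSO log2 difference of 6 genes (vertical) in the 4 lines (horizontal), where points are the 5 times in order from left to right and the bar is their mean with the SD over times. FOXA2 lay at -2.37 in REC1, and CCND1 at a measured -1.74, which stands for at least 2.20-fold since 0 OTX015 arrays of REC1 detected it. Both lay between -0.13 and 0.05 in the other lines, of which those without a detected signal read near 0.

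The DMSO arrays alone were compared between times. From 2 h to 24 h in DMSO, 597 genes rose and 427 fell, but 6 and 22 did so by at least 2-fold. Chaperone genes were among the largest rises. HSPA1B rose by 1.82 (SE 0.35, n = 4 lines, limma adjusted p = 0.00466), CHORDC1 by 1.1 (SE 0.15, adjusted p = 0.000622) and HSPH1 by 1.03 (SE 0.14, adjusted p = 0.000536), and FLI1, a transcription factor, and TRMT1L, a tRNA methyltransferase relative, rose by 1.03 each (adjusted p = 0.00155 and 0.000882). Falls were those of GSTA2, a glutathione transferase (-2.16, SE 0.64, adjusted p = 0.0494), the pseudogene CMAHP and DBNDD2 (-1.80 each, adjusted p = 0.0333 and 0.00369), the early response gene FOSB (-1.58, adjusted p = 0.00728) and SYS1 (-1.47, adjusted p = 0.00357). The background level of the arrays also differed, with 106.4 ± 3.32 at 2 h and 97.9 ± 4.38 at 24 h in DMSO, and a change in culture was not separated from such effects of the arrays.

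Several of these genes did not pass with 3 lines, though their changes stayed similar. GSTA2 had -1.83, -2.22, -2.22 and -2.37 without GRANTA519, JEKO1, MAVER1 and REC1 (adjusted p = 0.188, 0.0765, 0.127 and 0.0628; range over 11 alternatives 0.0241 to 0.188). CMAHP had -1.89 without GRANTA519 (0.105) and -1.71 without MAVER1 (0.148), and without MAVER1 HSPA1B had 1.54 (0.0693), DBNDD2 -1.69 (0.0663) and FOSB -1.64 (0.0651). CMAHP was at -0.62 with the mean of its probes, which disagreed (0.163, range 0.0118 to 0.163), and TRMT1L at 0.58. The ranges for HSPA1B, DBNDD2 and FOSB began at 0.00123, 0.000875 and 0.00269 and ended without MAVER1, and FOSB fell by 1.04 without GRANTA519. The count of 1024 was 497 without GRANTA519, 209 without MAVER1 and 437 without REC1.

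The lines themselves differed in DMSO in 10113 genes, a comparison of signals between lines without the inhibitor. These p-values too measure the spread over the 5 times and not over cultures of a line. Among the genes with the smallest p-values, HLA-DPA1 had 12.41, 10.89 and 12.06 on the log2 scale in GRANTA519, JEKO1 and MAVER1 and was not detected in REC1 (adjusted p = 9.36e-23), and HLA-DRA had 13.30, 12.81, 12.87 and 6.13 (adjusted p = 8.6e-22). TCL1A, a coactivator of AKT kinases, had 8.59, 12.37 and 10.57 and was not detected in REC1, while TCL1B had 5.19, 12.65, 12.26 and 5.63 (adjusted p = 4.97e-21 and 1.23e-20). CCND1 had 10.56 in GRANTA519, 13.31 in MAVER1 and 6.10 in REC1 and was not detected in JEKO1 (adjusted p = 4.97e-21). Since 0 other CCND1 probes passed the detection filter, a low or absent signal need not mean a low level of its transcript. CAMP, an antimicrobial peptide gene, had 11.50 in REC1, and the T cell receptor gene CD3D had 10.05 in REC1 alone, as CTCFL, a paralogue of CTCF, had 10.59 in JEKO1 alone (adjusted p = 1.23e-20, 1.23e-20 and 4.97e-21). Without REC1 CD3D did not differ (adjusted p = 0.752, range over 12 alternatives 2.51e-23 to 0.752), nor did CTCFL without JEKO1 (0.786, range 1.37e-23 to 0.786). Among genes detected on all 40 arrays the count was 6519.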

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

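Of the tests here, those of CCND1 in REC1, and those of histone classes and of DNA replication genes for the histone rise, were chosen after the result was seen. The others were fixed before it was seen.

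Far fewer genes changed at 2 h (1347) than at 24 h (3373). The 2 h arrays had the higher background (101.4 to 110.3, against 90.95 to 101.3 at 24 h), which could hide changes of dim genes, but among the 3490 brightest genes the 24 h count was still 3.23 times the 2 h count (379 against 1226), and 4.09 to 6.86 times with a line left out. An exchange of the OTX015 and DMSO array of a line at 2 h is argued against by the correlation across genes of each line's 2 h differences with the 4 h differences of the other lines, whose lowest value was 0.303. A response that builds up with time remains as a hypothesis. In the change from 2 h to 24 h 1559 effects passed, against at most 113 in another order of the times.

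CCND1, the gene of cyclin D1, was lower with OTX015 in REC1 by a measured log2 difference of -1.74 (at least 2.20-fold), far from the other lines in the set of 4. A probe at background in the other lines could give this, but 2 of them, GRANTA519 and MAVER1, were detected on all 5 DMSO arrays at a level above REC1, whereas JEKO1 was itself at background and shows nothing. A single mislabelled REC1 array is argued against by a fall past -0.5 at 5 of 5 times. Whether the probe reads a part of the transcript, or a related one, that differs between lines cannot be told apart from a change of CCND1 itself, because 0 other CCND1 probes passed the detection filter. A difference between the lines in how CCND1 is driven may lie behind the pattern and stays open as a hypothesis.

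Of 20 measured histone genes 18 rose, with a median of 1.18. Transcripts of near-identical copies may bind each other's probes, but all 5 histone classes (H1, H2A, H2B, H3 and H4) held a member that rose, so 1 transcript cannot account for it. Such binding within a class is not excluded, so the 18 rises need not be separate. A larger share of cells in S phase might raise replication genes too. The largest rise among G1/S and DNA replication genes was 0.465, for GINS4, chosen after its value was seen. At 24 h, where the histone median was 1.64, 0 of 43 replication genes rose and 9 fell. Their median was then -0.14 (camera adjusted p = 0.0124, but 0.502 with an estimated correlation). At 8 h, where the histone median was 1.31, 9 rose and 4 fell. How far replication genes rise beside histone genes in S phase is not known from these data. A larger share of such cells therefore stays open. Quantile normalization is argued against by a median of 1.16 with arrays scaled to a common median. A change in how histone transcripts end or are tailed, which the cRNA labelling could read as a rise, was not tested and stays open beside a higher level.

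A gap of 1 line to the others exceeded Dixon's 95% limit in 2 of 91 groups, CCND1 above and H4C15, which rose least in REC1 (0.97), and chance marks about 1 in 20 such groups. Differences between lines marked these genes among the largest changes over all times, with adjusted p of the F test of 0.000702 for EFR3B, 0.0347 for H2BC21, 0.00905 for H2AC6, 0.00149 for H4C14, 0.000107 for H4C15, 0.000739 for PPP1R13B and 0.0276 for H2AC18. For genes that fell, these were 0.0456 for TNFRSF17, 0.00881 for SLC2A5, 0.0147 for FCMR, 0.0202 for TLR10, 0.00796 for PCED1B, 0.00365 for ESPNL, 0.00401 for CD72 and 0.0446 for SH3TC1. EFR3B was detected on 0 DMSO arrays of each line, and TNFRSF17 on 0 OTX015 arrays of JEKO1. The sizes of their changes therefore cannot be compared between lines. Among the genes always reported they were 0.000972 for MYC, 1.31e-06 for CCND1, 0.0257 for BTK, 0.0173 for CD79A and 0.0193 for CD79B.

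Differences between times marked rises with adjusted p of 1.61e-06 for EFR3B, 0.00834 for H4C14, 0.00173 for H4C15, 0.0207 for PPP1R13B, 0.00671 for H2BC11, 0.037 for ZSWIM6 and 0.00319 for H2AC18. Among falls they were 0.0251 for TNFRSF17, 1.36e-05 for SLC2A5, 9.19e-06 for NAPSB, 0.00115 for GAPT, 1.17e-06 for FCMR, 1.17e-06 for ACSL5, 1.48e-06 for SLC15A3, 0.00908 for PCED1B, 0.0015 for ESPNL, 0.000147 for CD72 and 2e-04 for SH3TC1. BCL6 had 0.0177 and BTK 0.00279. Signals in data that the comparisons did not use came from 8806 detected probes unnamed here, of which 747 passed the threshold over all times, 418 higher and 329 lower.

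Other splits of the arrays were counted for every comparison, and in each 1 split, the real one, gave a count as large as the real count. At each time 35 splits of the 8 arrays, with the cell line in the fit, gave at most 0 genes against 303, 1816, 2743, 1908 and 2008 at 2, 4, 8, 12 and 24 h. Of these splits 3 could not be fitted, and the 8 that part all 4 pairs gave at most 0 besides the real one. Over all times, 100 exchanges within pairs gave 3967 genes for the real one and at most 1675 for another. Within GRANTA519, JEKO1, MAVER1 and REC1, 100 splits each gave 2877, 1894, 2313 and 2074 against a highest other of 1709, 485, 0 and 693, and the 13, 13, 14 and 12 splits that part all 5 pairs gave at most 0 besides the real one. For differences between lines, between times and from 2 h to 24 h, the real values of 1308, 1542 and 1559 stood against 53, 70 and 113. DMSO lines gave 10113 against 4484. At 1 time or in 1 line, the splits that part all pairs, with which a paired comparison has to be compared, are too few for a share under 0.05. Whether the times of a line came from separate cultures is not given in the sources used here. With whole lines exchanged, the 8 splits over all times gave 3967 and at most 0 besides the real one, which are also too few, and the 2 comparisons between lines have no other split. For the counts between times and from 2 h to 24 h, a chance order is argued against if the times of a line are exchangeable. Effects shared by the arrays of a time, such as the higher background at 2 h, are not excluded by this. DMSO at 24 h against 2 h gave 1024 genes, but 1022 in another order of the times.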

How the results depend on the processing

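Of the alternatives, leaving out the JEKO1 pair at 12 h, and leaving out the 2 h arrays in the tests between lines and between times, of DMSO lines and of lists, were chosen after seeing the data. Of 217 counts under an alternative 176 lay within 1.5 times the reported count and 41 did not. Differences between times went from 1542 to 2367 without background correction, to 2364 with the series matrix and to 503 without the 2 h arrays. With detection required on all 40 arrays, which tests fewer genes, differences between lines went to 687, DMSO lines to 6519 and lists past the threshold to 6. The tests were paired within line and time. With no replicate block the counts at 2, 4, 8, 12 and 24 h fell to 57, 213, 226, 238 and 330, since differences between lines then enter the spread, and 18 calls of named genes were lost. With the line but not the pair as replicate block, or the line as a random block, no count moved that far and no call of a named gene changed. With the spread of 1 time alone the counts were 303, 1816, 2743, 1908 and 2008 at 2, 4, 8, 12 and 24 h, of which that at 8 h lay within 1.5 times the reported one. Taking the 20 differences as independent gave 6126 genes over all times. REC1 without the 24 h arrays had 1405 genes, and with an estimated correlation 0 lists passed. That list test has few degrees of freedom. The cause was not tested where none is given.

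Leaving out 1 line at a time gave 608 to 1096 genes at 2 h, 1705 to 2247 at 4 h, 1867 to 2458 at 8 h, 1973 to 2492 at 12 h, 2249 to 2902 at 24 h and 2419 to 3299 over all times. Ranges were 641 to 836 between lines, 495 to 969 between times, 674 to 1396 from 2 h to 24 h, 209 to 890 for DMSO at 24 h against 2 h, 8768 to 9424 for DMSO lines and 14 to 16 for lists. With 3 lines fewer degrees of freedom remain. For named genes 3838 values kept their direction and side of the threshold, 121 lost and 31 gained the call, and 1 reversed, RPL13 over all times, at -0.032 (adjusted p = 0.735) with the mean of its probes, which differ in sign. For lists 388 kept it, 27 lost it and 3 gained it. No scaling moved the share of rises by over 10 percentage points or the median of all genes by over 0.1. Each scaling brings the arrays to a common level, so a gain or loss shared by all transcripts could not show in these values. With median scaling the rises and falls were 1475 and 1329 at 4 h (reported 1360 and 1383). At 24 h they were 1549 and 1719 (reported 1808 and 1565). Signal over background limits the size of changes. Without background correction 99 of 168 named changes of at least 2-fold shrank by over 1.5 times, and 121 did with the series matrix. A block for the slide was not run, since the slide is not given in the sources used here.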

Other observations

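The tests of gene families and the genes called in opposite directions were chosen after the data were seen; the tests of gene length and of starting level were fixed before their results, but the genes used for the latter were chosen after. Genes of the mitochondrial ribosome, which translates the proteins encoded in mitochondrial DNA, were lower with OTX015 over all times at the preset correlation, but not with an estimated one (adjusted p = 0.924). The test with an estimated correlation has few degrees of freedom here too, so a failure in it does not decide. Among 86 families formed from shared symbols, those starting with MRPL had 21 of 50 members down and 2 up (median -0.17, limma camera adjusted p = 4.14e-05), and those starting with MRPS had 15 of 29 down and 1 up (median -0.23, adjusted p = 0.00544). Falls included MRPL3 (-0.65 ± 0.15, mean ± SD of 4 lines, adjusted p = 0.00188), MRPL24 (-0.62 ± 0.08), MRPS15 (-0.60 ± 0.12) and MRPS18B (-0.53 ± 0.12). A member that rose, MRPL20-AS1 (0.55 ± 0.13), is an antisense RNA and not a ribosomal protein gene. Small RNA genes of the Cajal body, which guide modification of spliceosomal RNAs, were higher, with 8 of 20 SCARNA members up and 0 down (median 0.39, adjusted p = 0.000474, but adjusted p = 0.924 with an estimated correlation), led by SCARNA8 at 1.22 ± 0.52 and SCARNA13 at 0.91 ± 0.30. The H/ACA small nucleolar RNA genes (SNORA) had 16 of 80 up and 4 down (median 0.18, adjusted p = 0.0121), and the C/D ones (SNORD) 17 of 93 up and 1 down (adjusted p = 0.0728), among them SNORD3A, SNORD3C and SNORD3D, which encode U3, at 1.08 to 1.22. The SNORA and SNORD families too had adjusted p = 0.924 with an estimated correlation.

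A few genes passed in opposite directions in different lines, 34 in all. ABCB9, a lysosomal peptide transporter, fell by 1.31 ± 0.34 in JEKO1 and rose by 0.85 ± 0.37 in REC1 (mean ± SD of 5 times, adjusted p between lines 1.17e-05). CCDC112 rose by 0.52 in GRANTA519 and fell by 1.22 in MAVER1 (0.000107), VPS37D rose by 0.85 in GRANTA519 and fell by 0.84 in JEKO1 (0.00122), and CADM1, a cell adhesion gene, rose by 0.58 in GRANTA519 and fell by 1.0 in JEKO1 (0.000639).

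It was tested whether long genes, which need longer elongation, fell more at 2 h. Spearman's correlation across genes of gene length with the 2 h change was at most 0.12, in MAVER1, and -0.019, 0.031 and 0.039 in GRANTA519, JEKO1 and REC1, over 13947 genes that are not independent replicates, so a tendency shared by the 4 lines is argued against. It was also tested whether genes expressed more in a line than in the others fell more in that line. Over 7952 genes detected on all 8 DMSO arrays of 2 and 4 h, the correlation of the starting level with the later effect was -0.142 in REC1 and -0.122 in GRANTA519. It was -0.0328 in JEKO1 and, highest, -0.000142 in MAVER1, which argues against a rule common to the 4 lines among these genes. Over all 13959 genes the values were -0.183, -0.16, -0.107 and -0.0528, all in the direction of the rule. Genes at background in a line cannot fall there, which itself pushes these values down. Genes that only 1 line expressed were outside the first set, so the rule is not decided for them.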
